A study of Cryptococcus neoformans H99 with 2 samples.

How the data were processed

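Poly(A)-selected RNA from Cryptococcus neoformans strain H99 was sequenced on an Illumina NextSeq 500, per the labels' protocols, as 1 untreated library and 1 library from cells given eltrombopag at 0.06 µg/mL. Per the labels' protocols, a culture grown for 3 h at 30 °C in rich YPD medium was split, one aliquot received the drug and the other received the solvent DMSO, and both were kept at 30 °C for 90 min. The labels call the second aliquot untreated, and that name is kept here. There was 1 library per group and therefore no replicate.

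The deposited table held 7100 transcripts. Its estimated counts per transcript, per the file headers and the decimals in the values, were not scaled to depth by the authors. Its FPKM values were length-normalized by the authors, per the file headers. The submitters' processing notes name Trimmomatic 0.36, MultiQC 1.2, Bowtie2 2.3.2 and RSEM 1.2.31 without a role or an order, and the genome build and annotation release were not given in the sources used here. The table also held a log2 fold change and an unadjusted p-value computed by the authors, per the file headers. The header of the authors' log2 fold change reads as untreated minus eltrombopag, but the values equalled the log2 ratio of eltrombopag over untreated less a constant (SD of the difference 0.000323 among transcripts above 500 counts in both libraries), so they were read in that direction. The tool behind the authors' p-value was not given in the sources used here.

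Transcript identifiers were used as deposited. 4 of them, all structural non-coding RNAs, matched locus tags of the reference and 7096 did not, so names came from the best UniProt hit that the table lists for each transcript. BLASTP gave a hit for 5077 transcripts, BLASTX alone for 153, and 1870 had no hit. The median identity of the hits was 38.3%, and 410 hits were Cryptococcus entries, so most names are those of the nearest annotated protein of another organism. The deposited descriptions lacked nearly every lower-case x and y together with the character before it, and search patterns were altered in the same way before matching. No coordinates were used, since no genome was given.

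Estimated counts were rounded to whole numbers. Rounding was added after a first run without it, in which 6901 transcripts were tested and the same numbers of 30 higher and 46 lower were called. Library sizes were scaled with TMM in edgeR 4.0.16 (R 4.3.3), giving factors of 0.991 for the untreated and 1.01 for the eltrombopag library. The log2 ratio of eltrombopag over untreated was computed with a prior count of 2 for the 6904 transcripts that, once rounded, had at least 10 counts in either library. Each ratio carried an exact 95% conditional binomial (Clopper-Pearson) interval, called the counting interval here. It covers counting error only, because PCR copies are not independent molecules and no second culture was sequenced. Where counts have decimals, it also leaves out the uncertainty in how reads were divided among transcripts. A transcript was called higher or lower when the log2 ratio was at least 1 in size and the counting interval excluded a ratio of 1. No significance test was made and no p-value was computed. All ratios compare these 2 libraries, not the conditions.

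Counts with decimals arise where reads were divided among transcripts. Transcripts whose deposited counts were whole in both libraries are said to have whole counts. Read-sharing partners were transcripts with the same UniProt hit, counts with decimals, and sums within 0.02 of a whole number in both libraries.

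30 gene lists were fixed before the data were examined, by gene identifier with symbol and by product pattern. The identifiers could not be matched to the transcripts, so Cryptococcus UniProt entries for the same symbols were used instead. CFT1 and CMT1 were not matched by symbol, because those entries name other proteins. These steps and small changes to patterns were made with the annotation in view, and some members fixed by identifier may be missing. 27 had at least 5 tested members. For each of these the median log2 ratio was placed among 10000 random lists of the same size matched on deciles of mean expression. A list stood apart when its percentile was below 2.5 or above 97.5. The other lists were the mitochondrion-encoded genes with 3 tested members, the reference genes with 3, and structural non-coding RNA with 0.

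The rule for named transcripts was also fixed before the data were examined. It took the 10 highest and 10 lowest annotated called transcripts with a mean scaled count of at least 50, the 2 highest and 2 lowest whatever their annotation, up to 4 members per list with the largest log2 ratio in size, and the members of the iron, capsule, virulence, sterol, efflux and reference lists. A transcript without a hit, or whose hit is described as uncharacterized, was not counted as annotated. 5 annotated transcripts qualified as higher.

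The method was tested on simulated Poisson counts for this comparison, drawn for the same transcripts at the same depths. The call was made for 50 of 50 transcripts simulated at 3-fold, 24 of 50 at 2-fold and 1 of 50 at 1.5-fold, a size below the threshold of the call, and for 6 of 6703 simulated without change. Lists shifted by a log2 ratio of 0.1 were placed above the range in 50 of 50 cases. Of 200 random lists of 20 members without a shift, 10 fell outside the range. The definition of the range fixes that share in advance. The simulation held counting error only. Counting intervals excluded a ratio of 1 for 4.55% of transcripts simulated without change, against 45.5% of tested transcripts in the data. The simulation therefore gives no error rate for the spread between real libraries or for lists whose members vary together.

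Alternatives fixed before the data were examined were scaling by total counts, DESeq2 1.42.0 size factors, other count filters, other prior counts, thinning of the deeper library, and log2(FPKM + 1). Alternatives added after the data were seen were transcripts with whole counts only, partners summed, random lists matched also on length, and list members left out by hand. Length matching first used 3 bins and was then changed to 5 after those values had been seen. With 3 bins cytosolic ribosomal proteins lay at percentile 7.74, heme synthesis at 4.46, and glyoxylate and fatty acid oxidation at 2.90, and these 3 lists lost their call with 5 bins too. Iron uptake lay at 100 with either. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.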

Results

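Transcript abundance was measured by RNA sequencing in Cryptococcus neoformans H99, an encapsulated basidiomycete yeast that causes meningitis, after exposure to eltrombopag. Eltrombopag is a small molecule that activates the human thrombopoietin receptor and is also known to bind iron. The untreated library held 23448329 and the eltrombopag library 25273732 assigned counts. The 10 most abundant transcripts took 6.81% and 6.69% of them. Pearson's r between the libraries across transcripts was 0.989 and Spearman's rho 0.994 on log2 scaled counts, a description in which transcripts are not independent replicates.

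The comparison asks which transcripts differed between the aliquot given eltrombopag for 90 min and the aliquot without it. In the eltrombopag library, the sugar transporter, respiratory chain, proteasome and chaperone lists had lower medians than matched random lists, although members of each went both ways. Single transcripts that were lower included hits to the glucose transporter RCO3, the polyol transporter PLT5, isocitrate lyase and the 4 succinate dehydrogenase subunits. The iron and siderophore uptake, sterol synthesis, cell wall and ribosome biogenesis lists had higher medians. Most of these differences were small. 83.1% of the 6904 tested transcripts lay within 1.2-fold of equal abundance, and 30 were called at least 2-fold higher and 46 at least 2-fold lower. The counting interval lay above a ratio of 1 for 22.4% and below it for 23% of tested transcripts. These shares cover all tested transcripts and are not matched on expression. Counting intervals narrow as counts grow, so a list of abundant transcripts can exceed the shares at a small shift. Among the cytosolic ribosomal proteins, 60 of 77 were lower by this measure at a median log2 ratio of -0.06. The interval counts given with each list are therefore descriptions, and the comparison with random lists rests on the medians. Of the 27 fixed gene lists, 4 lay above and 8 below the range of matched random lists. Lists of unrelated transcripts would place 1.35 outside it on average. Members of a real list can vary together and some lists share members, so 1.35 is not the number expected without a drug effect. With 1 library per group none of these differences has a replicate check.

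**Figure D1:**
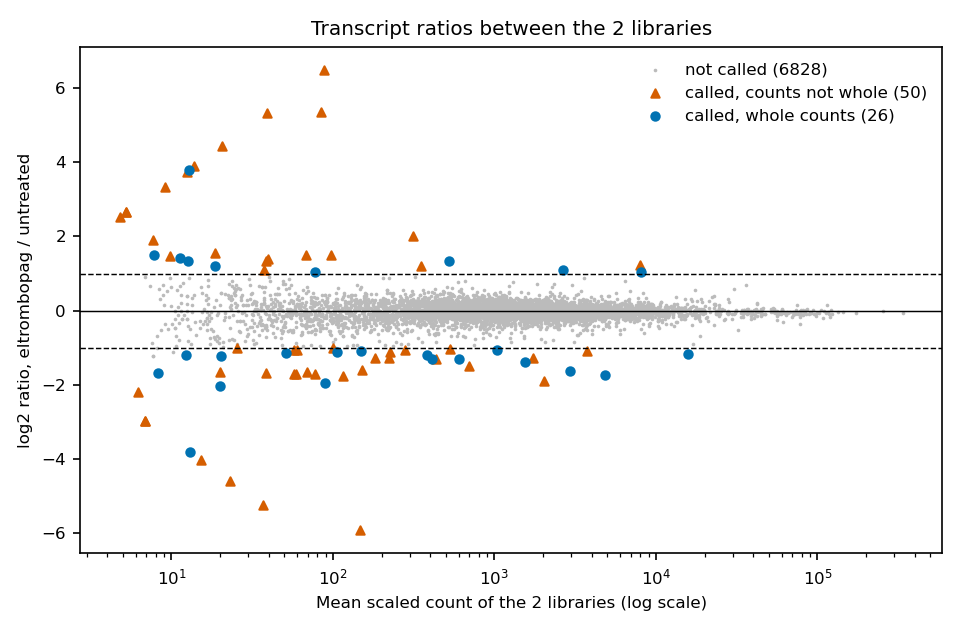
Log2 ratio of eltrombopag over untreated (y axis) against the mean scaled count of both libraries (x axis, log scale), 1 point per tested transcript; dashed lines mark 2-fold. Of the called transcripts, 26 had whole counts (circles) and 50 had counts with decimals (triangles), and the latter hold most of the largest ratios.

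The annotated transcripts called lower included transporters, enzymes and regulators. AFR93278, whose best hit is the glucose transporter RCO3 of Neurospora, had 7064 counts in the untreated and 2349 in the eltrombopag library, 3.30-fold lower (counting interval 3.15 to 3.46). AFR99093, a hit to the plant polyol transporter PLT5, was 3.06-fold lower (2.89 to 3.25). AFR97459, a hit to the ammonium transporter AMT1, was 2.80-fold lower (2.49 to 3.17), with counts that were not whole. AFR94564, a hit to isocitrate lyase (ACEA), the first enzyme of the glyoxylate cycle, was 2.47-fold lower (2.13 to 2.90). AFR96161, a hit to the cytochrome P450 FUM15, was 2.61-fold lower (2.42 to 2.83). AFR97378, a hit to the yeast retrograde regulator RTG3, was 3.90-fold lower on 137 and 37 counts (2.81 to 6.01). Leaving out hits described as uncharacterized, the remaining annotated transcripts among the 10 lowest were hits to the alcohol dehydrogenase ADH4, the nitrogen regulator NIT4, the protein UVRAG and the yeast membrane protein ASI1, between 2.45-fold and 3.28-fold lower, and the counts of these were not whole. The NIT4 hit AGV14515 shares reads with AFR96310, and their summed counts of 1137 and 1205 gave a log2 ratio of -0.05.

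Fewer annotated transcripts were called higher. AFR98585, a hit to a bacterial papain inhibitor, had 1614 and 3777 counts, 2.13-fold higher (2.01 to 2.26). AFR93265, a hit to the conidiation protein CON6, was 2.05-fold higher on 48 and 110 counts (1.48 to 3.00). AFR93678, a hit to CAX4, a dolichyl diphosphatase of protein glycosylation, was 2.82-fold higher (2.07 to 4.08) with counts that were not whole.

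The most extreme ratios belonged to transcripts with counts that were not whole. AGV15286, a hit to the Ras exchange factor GEFA, had 0 counts in the untreated and 184.84 in the eltrombopag library, at least 56.2-fold higher against a floor of 3 counts. Its partner AFR92378 had 365 and 212.16, and the sums of 365 and 397 gave a log2 ratio of -0.01. AGV14538, a hit to the sterol glucosyltransferase ATG26, had 2.33 and 173.65 counts, a ratio of 41.1 (21.6 to 660), while the sum with its partner AFR96473 was 1795 and 2182. AGV14272, which had no hit, had 278.64 and 2.52 counts and was 60.5-fold lower (34.5 to 498), and no partner could be assigned by hit. Read-sharing partners were found for 9 called transcripts, and over both libraries the called member held fewer counts than its partner in each pair. In 4 of the pairs, the hits to GEFA, MCR1, YFZ4 and YN8E, the partner differed in the opposite direction with a counting interval that excluded a ratio of 1. Calls were made for 1.65% of tested transcripts with counts that were not whole and for 0.673% of those with whole counts. The p-value in the authors' deposited table was under 0.05 for 43 transcripts, of which 35 had counts that were not whole.

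**Figure D2:**
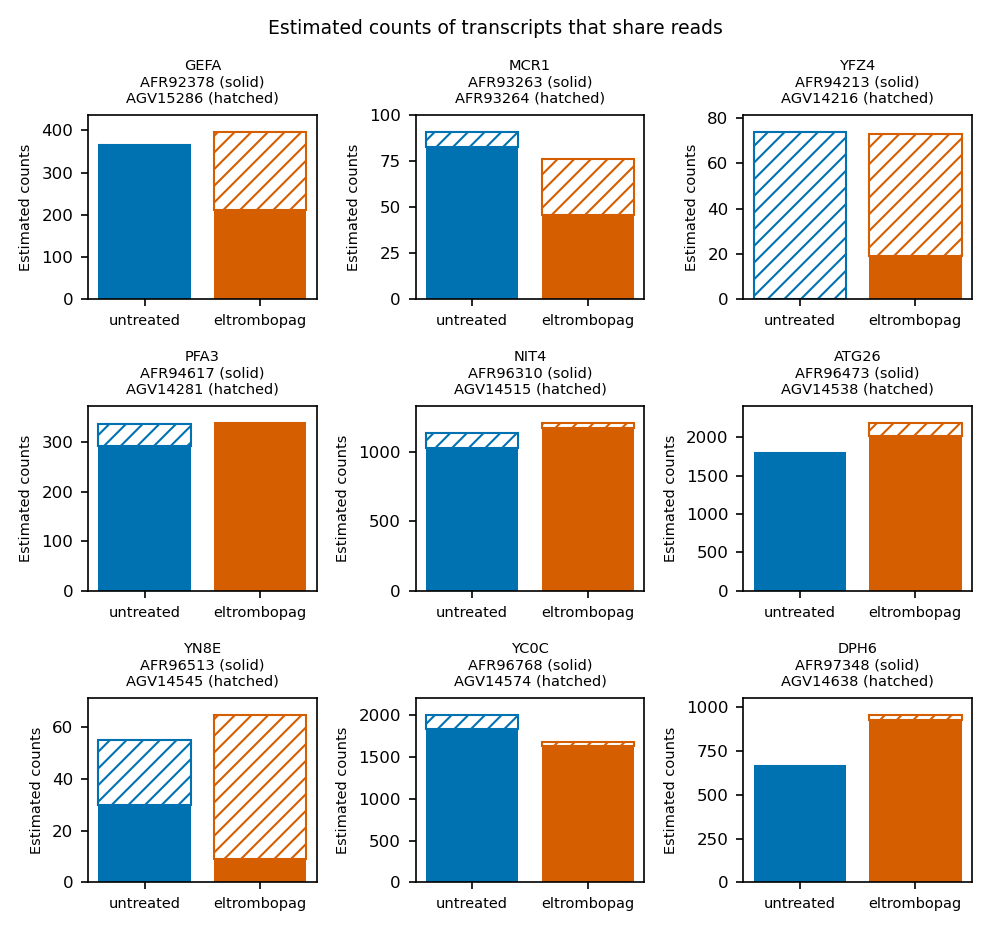
Estimated counts (y axis) in the untreated and eltrombopag libraries for the 9 pairs of read-sharing transcripts with a called member; solid and hatched bars are the members and their stacked height is the sum. In each pair the called member is the smaller one over both libraries.

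Iron uptake transcripts were higher as a group. The list of 19, made up of ferric reductases, iron permeases and siderophore transporters, had a median log2 ratio of 0.21 and lay above all 10000 random lists (percentile 100). 14 members were higher with a counting interval that excluded a ratio of 1, and 0 were lower by that measure. AFR96815, a hit to the siderophore transporter MIRB, had 1327 and 2374 counts and was 1.63-fold higher (1.52 to 1.75). AGV14567, a hit to the ferric reductase FRE2, was 1.39-fold higher (1.35 to 1.44). AFR98470, a hit to the iron permease FIP1, had 18582 and 26181 counts and was 1.28-fold higher (1.26 to 1.31). 3 hits to the iron multicopper oxidase FER1, the ferroxidase partner of such permeases, fell by pattern into the copper and zinc list and were singled out after their values were seen. Their log2 ratios were 0.24, 0.33 and 0.52. The copper and zinc list itself, with a median of 0.06, lay at the 88.9 percentile.

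The respiratory chain list had a lower median. The 69 tested members of the respiratory chain and ATP synthase list had a median log2 ratio of -0.11, below all random lists, with 36 lower and 9 higher by their counting intervals. Its 4 members with the largest ratios among well-counted transcripts were the subunits of succinate dehydrogenase, which joins the tricarboxylic acid cycle to the respiratory chain. The log2 ratios were -0.42 for the SDHA hit, -0.49 for SDHB, -0.43 for SDH3 and -0.50 for DHSD. The list of 20 iron-sulfur proteins and assembly factors had a median of -0.08 (percentile 1.5), with 9 lower and 1 higher. Among its members a 2Fe-2S ferredoxin hit (FER2, AFR94700) had -0.48, the complex I subunit NDUS8 -0.41 and the assembly factor ISA1 -0.38. The 10 transcripts of the heme synthesis list had a median of -0.11 (percentile 1.54), with 6 lower, among them HEM4 at -0.42, and 1 higher, HEM6 at 0.24. The lowest member, AFR94208, a hit to SUMT at -0.45, shares reads with AGV14213 at 0.05, and their summed counts gave -0.21. The iron-sulfur list lay at percentile 15.9 once the methyltransferase TMT1 was left out by hand, and the heme list at 2.97 when random lists were also matched on length.

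**Figure D3:**
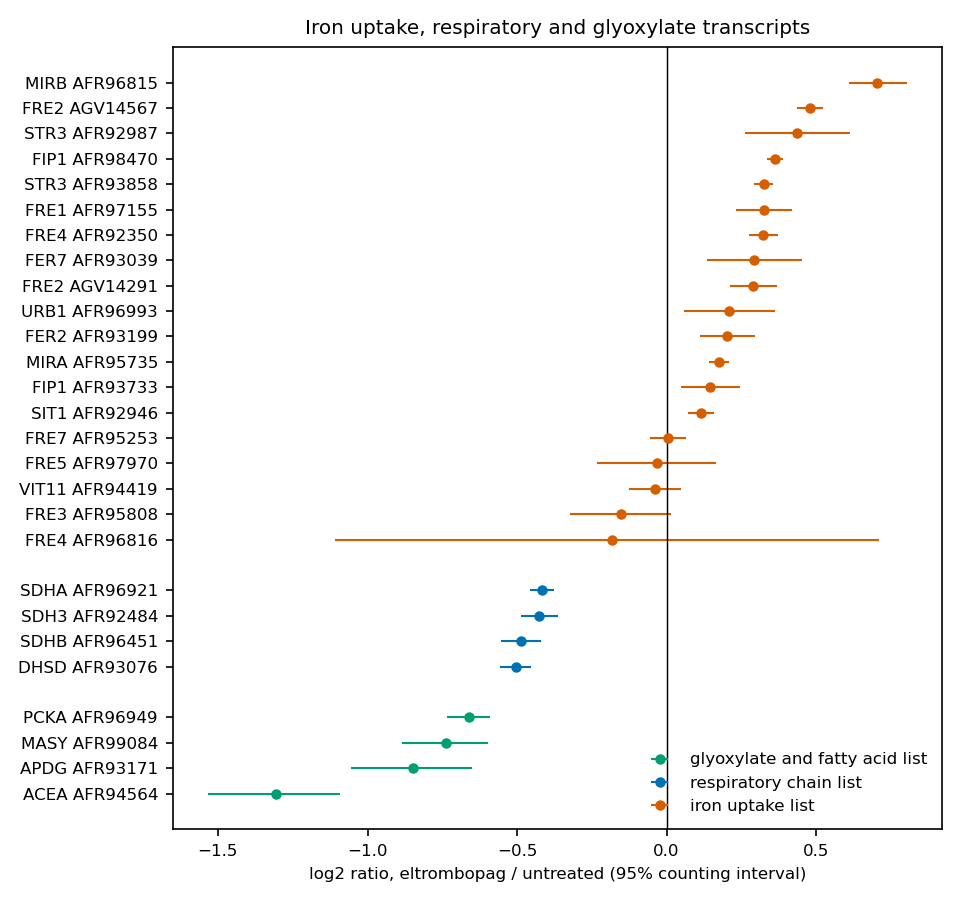
Log2 ratio of eltrombopag over untreated (x axis) with 95% counting intervals for the 19 members of the iron uptake list and for the 4 members named by rule from the respiratory chain list and from the glyoxylate and fatty acid list, labelled by best hit and transcript. MIRB stands highest at 0.71 and ACEA lowest at -1.30.

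The sugar transporter list had a median log2 ratio of -0.19 over 35 members, below all random lists. 10 were lower and 4 higher by their counting intervals. The product pattern also took in hits to the UDP-galactose transporter GMS1. One of them, AFR94404, was the highest member at 0.42 and is in the capsule list too. It shares reads with AGV14242 at -0.23, and their summed counts gave -0.02. With 31 members after hand editing, the list median was -0.21 (percentile 0.01). On log2(FPKM + 1) the list median was -0.09 (percentile 0.26). The wider Pfam family of sugar and other transporters, scanned after the data were seen, was more mixed. Its 87 tested transcripts had a median of -0.07, with 51 below 0 and 36 above (percentile 1.45 among length-matched random lists). Hits to yeast STL1 entered the sugar transporter list by product name, and what they transport was not measured. Besides RCO3, 2 STL1 hits with low counts (AFR93957 and AFR95554) had log2 ratios of -1.28 and -0.92, and another RCO3 hit (AFR98814) had -0.59. The most abundant STL1 hit, AFR97888, instead had 18834 and 27189 counts and was 1.32-fold higher (1.29 to 1.34), and AFR98031 had 0.17. The glyoxylate cycle and fatty acid oxidation list had a median of -0.10 (percentile 1.97), with 10 of 19 lower and 0 higher. Malate synthase (MASY), the enzyme after isocitrate lyase, was 1.67-fold lower (1.51 to 1.84), and phosphoenolpyruvate carboxykinase (PCKA), which starts gluconeogenesis, was 1.58-fold lower (1.51 to 1.66). This list lay at percentile 15.4 among transcripts with whole counts. Glycolysis, with a median of -0.01, lay within the random range, and so did the tricarboxylic acid cycle list at -0.05 (percentile 11.2) despite its succinate dehydrogenase members. On its 6 members with whole counts the glycolysis list instead lay below that range (percentile 2.13).

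The proteasome and chaperone lists had lower medians, with no member called. The 38 proteasome members had a median log2 ratio of -0.13, below all random lists, and 31 were lower by their counting intervals against 1 higher. The chaperone list of 53 had a median of -0.09 (percentile 0.03), with 26 lower and 8 higher. The HSP70 family hit HSP71 was 1.62-fold lower (1.58 to 1.65), the disaggregase HS104 1.43-fold lower (1.41 to 1.45) and its mitochondrial relative HSP78 1.42-fold lower (1.37 to 1.46). The small heat shock protein hit HSP12 was instead 1.47-fold higher (1.44 to 1.5). The 77 cytosolic ribosomal proteins had a median of -0.06 (percentile 0.225), but lay within the random range at percentile 11.9 when random lists were also matched on length. Across transcripts the log2 ratio was higher for longer transcripts (Spearman's rho 0.2 with length), while rho with mean expression was -0.02.

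The ribosome biogenesis, sterol and cell wall lists had higher medians, with no member called. The 70 ribosome biogenesis transcripts had a median of 0.07 (percentile 99.98), with 31 higher and 6 lower. AGV15370, a hit to the rRNA processing factor UTP7, was 1.63-fold higher (1.60 to 1.65), with counts that were not whole. The 15 ergosterol synthesis transcripts had a median of 0.11 (percentile 99.8), with 8 higher and 1 lower. The sterol C4 oxidase hit MSMO had a log2 ratio of 0.28 and the C5 desaturase hit ERG3 0.24, while the azole target CP51 had 0.04. The 42 transcripts of the cell wall list had a median of 0.10 (percentile 99.98), with 22 higher and 8 lower. Its product pattern also took in enzymes outside the wall, such as the glycogen branching enzyme GLGB at -0.37. With 40 members after hand editing, the list median was 0.11 (percentile 99.99). The alpha-glucan synthase hit AGS1 (AFR96345) was 1.70-fold higher (1.57 to 1.84) with counts that were not whole, and summed with its more abundant partner AGV14519 it had a log2 ratio of 0.30. The glucan 1,3-beta-glucosidase hit EXG had -0.55 on 129 and 96 counts.

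**Figure D4:**
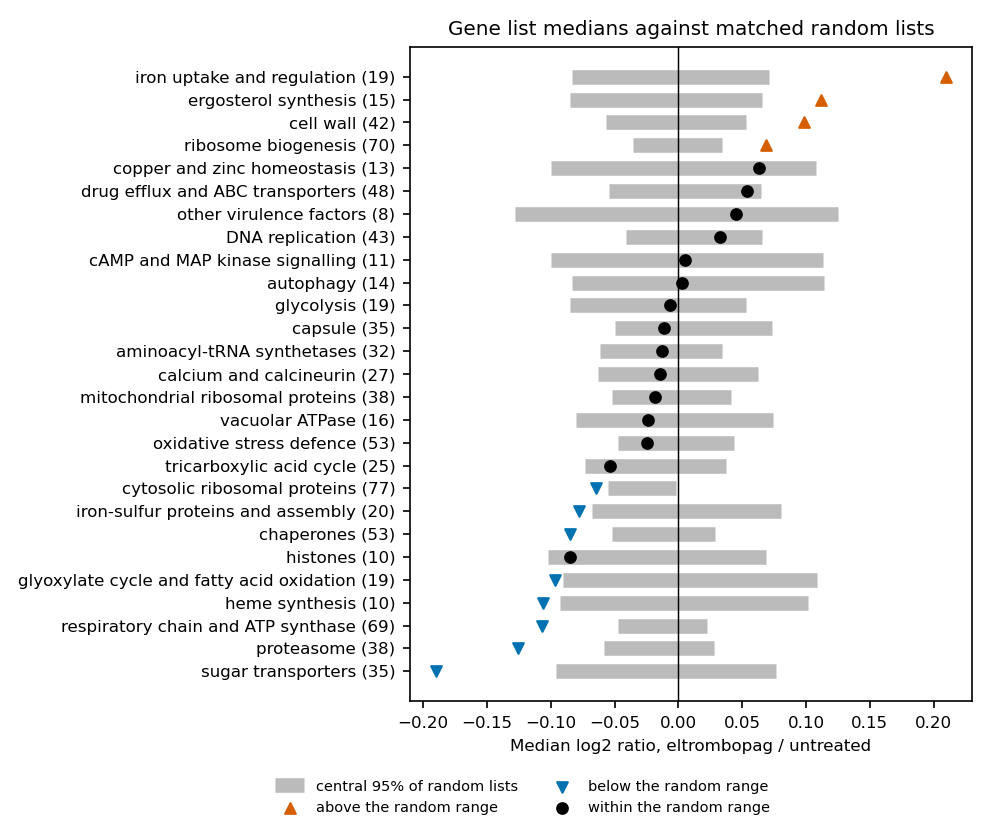
Median log2 ratio of eltrombopag over untreated (x axis) for the 27 fixed lists with at least 5 tested members, number of members in parentheses; grey bars span the central 95% of 10000 random lists matched on expression. The iron uptake list stands farthest above at 0.21 and the sugar transporter list farthest below at -0.19.

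Virulence-related and drug efflux lists lay within the random range. The capsule list of 35, mostly mannosyltransferases, had a median of -0.01. Its product pattern also took in hits such as ALG1 and OCH1 that are not specific to the capsule, so the median does not speak for capsule genes alone. The other virulence factors had 0.05 over 8 members, among them laccase LAC1 at -0.25, LAC2 at 0.26, urease (UREA) at 0.07 and phospholipase PLB1 (AFR98312) at 0.12. LAC2 rested on 124 and 163 counts, and its counting interval included a ratio of 1. The drug efflux and ABC transporter list of 48 had a median of 0.05 (percentile 94.7). Its one called member, AGV14751, a hit to the ABC transporter ZRA1, was 2-fold lower (1.51 to 2.77) on 128.49 and 68.88 counts, while another ZRA1 hit, AFR93598, had 0.51. The highest member, AFR96699, had 0.64 on 27.87 and 49.23 counts, and its counting interval included a ratio of 1. Histones had -0.09 (percentile 5.35), DNA replication 0.03, oxidative stress defence -0.02, calcium and calcineurin -0.01, cAMP and MAP kinase signalling 0.01, autophagy 0.00, vacuolar ATPase -0.02, mitochondrial ribosomal proteins -0.02 and aminoacyl-tRNA synthetases -0.01, all within the range. Reference transcripts had log2 ratios of -0.03 for actin, -0.07 for elongation factor 1-alpha and -0.16 for glyceraldehyde-3-phosphate dehydrogenase. Among mitochondrion-encoded transcripts, which poly(A) selection captures poorly, 3 of 14 were tested, and the one called, COX1, rested on 3 and 13 counts. The 4 structural non-coding RNAs had 0 counts in both libraries.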

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

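The whole-count, partner-summed, length-matched and hand-edited alternatives were chosen after the data were seen; the others were fixed before the data were examined. The 30 higher and 46 lower calls stayed within 1.5 times under both other scalings, no filter, both other prior counts, thinning and summed partners (21 to 32 higher, 37 to 49 lower). They became 15 higher with the 50-count filter, where 34 were lower, 13 higher and 18 lower on log2(FPKM + 1), which shrinks low values by construction, and 9 higher and 17 lower among transcripts with whole counts, where fewer were tested. With the 50-count filter Pearson's r was 0.990 and Spearman's rho 0.993.

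Of 213 list values under an alternative, 204 kept their call, and 8 of the 12 lists that stood apart did so in the same direction under every alternative run. Cytosolic ribosomal proteins lay at percentile 14.2 on FPKM, 4.70 with whole counts and 11.9 with length matching. Heme synthesis lay at 2.64 on FPKM and 2.97 with length matching, and had too few members with whole counts for a value. Iron-sulfur proteins lay at 15.9 with hand-edited members. Glyoxylate and fatty acid oxidation lay at 15.4 with whole counts and 3.68 with length matching. Glycolysis, within the range at 58.0, lay below it at 2.13 with whole counts, on 6 of its 19 members. Of the values with a changed call, this was the 1 that also crossed the middle of its random lists, although the list median was below 0 in both. The cause of these changes was not tested. Of the named transcripts, AGV15286 reversed to a log2 ratio of -0.0119 when summed with its partner, by construction, and 1804 of 1843 values lay within the counting interval of the value reported. No paired analysis was possible because each group had 1 library. A call needs a 2-fold difference, so smaller ones show only in counting intervals and list medians.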

Other observations

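Several further groups stood apart in a scan of 118 Pfam protein families with at least 10 tested transcripts, chosen after the data were seen. Its first run matched random lists on expression only, and 12 families lay above and 9 below the random range. Length matching was then added, which left 7 above and 4 below. Lists of unrelated transcripts would place 5.90 outside the range on average, and some families share members, so single families carry little weight. The families and members named here were picked after their values were seen. The 16 transcripts with the amino acid permease domain had a median log2 ratio of -0.14 (percentile 1.61), led by AFR95028, a hit to the acidic amino acid permease DIP5, at 818 and 365 counts, 2.45-fold lower (counting interval 2.17 to 2.79). The family was mixed, with 11 members below 0 and 5 above, and another DIP5 hit, AGV15328, had 0.21. The 11 alpha-amylase family transcripts had a median of 0.24 (percentile 100), of which 3 were already in the fixed lists. The maltase hit MALT had 0.28 and the amylase hit AMYA1 0.30, whereas the glycogen branching enzyme GLGB had -0.37 and the amylase hit AMY2 -0.82 on 16.3 and 8.95 counts. All 10 transcripts with a response regulator receiver domain, found in fungal two-component signalling, had log2 ratios above 0, with a median of 0.16 (percentile 98.6).

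Among transcripts with whole counts and no UniProt hit, AFR93989 was the most abundant one called. It had 20731 and 10150 counts, 2.24-fold lower (2.19 to 2.29), and carries a BAG domain, a module that binds HSP70 chaperones. AFR95862 had 5011 and 11330 counts, 2.06-fold higher (1.99 to 2.13), with no Pfam domain listed. Of 7 protein classes also scanned after the data were seen, 5 lay outside their random lists. The classes overlap, and those with and without a signal peptide are complements, so the 5 are not independent. Transcripts with a predicted signal peptide (median 0.02), with 1 to 9 helices (0.01), without a hit (0.02) and with a signal peptide but no hit (0.04) lay above, and those without a signal peptide (0.00) below. AGV14640, a hit to glutamate synthase GLT1, had 1338 and 700 counts and was 2.09-fold lower (1.91 to 2.3).

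The tests on whole counts were chosen after the values they measure were seen. The length and iron-binding tests were set before their own values were computed, but after the patterns had been seen, and with the values of a few iron-binding members such as FUM15 already known. The demand that the iron-binding result hold without called members, and its length matching, were added after its value of 2.29 was seen.

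The first pattern is the set of transcripts at least 2-fold apart. Of these, 50 had counts that were not whole, 9 with an identified partner and 41 without. In 4 of the 9 pairs the partner differed in the opposite direction with a counting interval that excluded a ratio of 1. A different division of reads and a different use of isoforms would both give such a redistribution within the pair. No explanation was tested for this pattern.

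The second pattern is the iron uptake list above, and the respiratory chain list below, their random lists, while the iron-sulfur list (15.9 with hand-edited members) and the heme list (2.97 with length matching) did not keep their place. The iron uptake list stayed at percentile 100 among its 15 members with whole counts. Such members have no visible read division by definition, so the value argues only against visible division as the sole source of the pattern. The test did not cover the other members, and reads divided in whole numbers would pass it unseen. The list also stayed at percentile 100 with length-matched random lists, which argues against transcript length. Eltrombopag binds iron, but whether 0.06 µg/mL in rich YPD medium lowers available iron was not measured. Reduced iron availability may account for both directions. It was tested on 65 transcripts with iron-binding domains outside the fixed lists, whose median of -0.05 lay at percentile 2.29, but at 2.66 without the called FUM15 and at 4.99 with length matching, so the hypothesis stays open. A difference between the 2 aliquots unrelated to the drug cannot be told apart from it with 1 library per group.

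The third pattern is the sugar transporter list below its random lists. Among the 13 list members with whole counts the median lay at percentile 0.23, which argues against reads shared between paralogs for those members. The test did not cover members whose counts were not whole, and reads divided in whole numbers would pass it unseen. Lower sugar transporter, isocitrate lyase, malate synthase and phosphoenolpyruvate carboxykinase transcripts may reflect the drug or a small difference in how far each aliquot had used its medium, and 1 library per group leaves these open. No biological explanation was tested for this pattern.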
